A study of Homo sapiens with 5 samples.

How the data were processed

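HL60 cells were crosslinked, digested with HindIII and ligated in solution, per the labels' protocols. Reads were aligned with Bowtie, filtered with HiCUP and counted into matrices with HOMER, per the series' design text; HOMER 4.7 and the genome build hg19 are named in the submitters' processing notes. The series' design text prints the HiCUP version as v0.5.826, and the Bowtie version and the settings of the filters are not given in the sources used here. The authors deposited 3 all-by-all matrices of raw contact counts between 6203 bins of 500 kb, per the file headers and the values, which are whole numbers without normalization. The ATRA matrix holds 1 library, and the untreated and TPA matrices each hold 2 libraries merged, per the labels. Because the merged libraries cannot be separated, each condition is a single measurement. How cultures and libraries were batched is not given in the sources used here, and each condition has its own libraries, so library and treatment effects cannot be separated.

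Values on the diagonal, where each contact within a bin is counted from both ends, were divided by 2. The untreated matrix had 1 cell that differed from its mirror, and the upper triangle was used. Of 6203 bins, the 6083 on the autosomes and chromosome X were analysed. The others held 0.0513% of untreated, 0.101% of ATRA and 0.0811% of TPA contacts. The median bin with contacts held 3463 contacts in untreated cells, 3273 in ATRA and 3467 in TPA, and a pair of bins held 0.574, 0.521 and 0.563 contacts on average. At this depth single bin pairs far from the diagonal carry little information, and sums over chromosomes, distances or compartments are precise to counting error. No p-value is given, and the intervals cover counting error only. PCR duplicates and other non-independent read pairs are not covered by the intervals.

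Shares of contacts carry exact binomial 95% intervals. Decay with distance was computed from raw contacts over all bin pairs of each chromosome, in classes with limits at 2, 10 and 50 Mb and as slopes of the log mean contacts per bin pair on log distance. For compartments, bins under 0.2 times the median coverage in any matrix were left out, which kept 5630 bins, and each matrix was balanced in 60 iterations so that all bins had equal coverage. Balanced contacts were divided by the mean at the same distance, and the first eigenvector of their correlation matrix was taken per chromosome, or the second where the first followed the chromosome arms at a correlation above 0.7. The sign was set on the summed matrix by contact with chromosome 19, or with chromosomes 17 and 22 for chromosome 19 itself, and each matrix followed it. Saddle strength compared the top and bottom 20% of bins. Contacts between chromosomes were divided by an expectation fitted to the coverage of each chromosome by iterative proportional fitting. Coverage runs needed at least 3 bins above 2.5 or below 0.4 times the median in all 3 matrices. Joined segments were bin pairs on different chromosomes with at least 20 contacts in the summed matrix at 10 or more times the expectation from coverage, with neighbours merged. For bin pair differences within chromosomes, at least 1 Mb apart, the expectation was the mean at the same distance.

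Counting spread was estimated from 10 Poisson resamples of each matrix, or 200 for values between chromosomes, and counting noise from 5 random assignments of all contacts to the conditions; neither contains variation between cultures. The compartment rule recovered 95.5% of 200 switches planted in simulated data at ATRA depth and 97% at TPA depth over 5630 bins, with 0 elsewhere. Each planted switch was a full change of sign, in simulated matrices that held coverage, distance decay and compartments only. The sign of each simulated eigenvector was taken from the known pattern. Errors of eigenvector or sign in the real matrices are therefore not covered by these rates. The bin pair rule recovered 100% of 100 pairs planted at 4-fold in each of ATRA and TPA. Of those planted at 3-fold it recovered 90% in ATRA (9905 pairs tested) and 95% in TPA (11573 pairs tested). Changes below 3-fold were not planted, so recovery closer to the limit of the rule was not tested. The rates are not split by number of contacts or by direction, so they may not hold for all pairs tested. The rule for joined segments recovered 20 of 20 planted joins, with 1 cluster elsewhere.

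Named regions follow a rule set before the data were examined. It takes the 5 largest rises and falls of compartment score among switching bins, the 5 highest, most raised and most lowered chromosome pairs, all bin pairs past the rule, the 10 joined segments with the most contacts, and up to 10 coverage runs. The list without chromosomes 14 and 21 was added after the data were seen, since their eigenvectors differed between matrices. Gene lists had been planned, for granulocyte, macrophage, promyelocyte, rheumatoid arthritis, erythroid, lymphoid, fibroblast and housekeeping genes. They are not analysed here because the gene table used here is on another genome build, so no gene was placed in a bin. Alternatives were other distance, balancing, bin size, depth, threshold, eigenvector and coverage settings, and their effect is given in the closing section. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.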

Results

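Genome-wide chromosome contacts were measured by in-solution Hi-C in HL60, an established human promyelocytic leukemia cell line. Hi-C joins DNA fragments that lie close together in the nucleus and counts the joined pairs. The cells were untreated, treated with all-trans retinoic acid (ATRA), which drives HL60 toward granulocyte-like cells, or treated with the phorbol ester TPA, which drives them toward macrophage-like cells. The 5 samples form 3 conditions, with 2 untreated libraries, 1 ATRA library and 2 TPA libraries, and each condition is held in 1 matrix of raw contact counts between 500 kb bins on hg19. The untreated and TPA matrices each pool their 2 libraries, so no spread between replicates could be computed, and no p-value is given. All intervals cover counting error only and describe these libraries, not the conditions in general. On the autosomes and chromosome X, the untreated matrix held 10628045 contacts, the ATRA matrix 9632300 and the TPA matrix 10423501. The title of the series concerns intergenic variants from an association study of rheumatoid arthritis; no variant is analysed here.

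Contacts shifted from within chromosomes to between chromosomes in both treated matrices. Contacts within a chromosome made up 39.0% of untreated contacts (95% exact binomial interval 38.9 to 39.0), 31.5% of ATRA contacts (31.5 to 31.6) and 36.3% of TPA contacts (36.3 to 36.3). The difference from untreated cells was -7.41 percentage points in ATRA (-7.45 to -7.37) and -2.65 points in TPA (-2.69 to -2.61). Contacts of mitochondrial with nuclear DNA, outside these chromosomes, were more frequent in both treated matrices, at 339.7 for every 1000000 contacts in untreated cells, 836.9 in ATRA and 639.9 in TPA. Contacts within a single bin were 8.40% of the untreated, 5.99% of the ATRA and 7.07% of the TPA contacts.

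Short-range contacts were less frequent in both treated matrices, on every chromosome tested. Of contacts between different bins of a chromosome, those less than 2 Mb apart made up 36.0% in untreated cells, 28.2% in ATRA and 27.6% in TPA. The share was lower than in untreated cells on 23 of 23 chromosomes in each treated matrix. Chromosome 14 showed the largest difference in both, from 44.9% to 34.9% in ATRA and 33.7% in TPA. Chromosome 21 showed the smallest in ATRA, from 59.8% to 55.3%, and chromosome 20 the smallest in TPA, from 42.0% to 35.8%. Relative to the total of each matrix, contacts between adjacent bins in ATRA were 0.633 times those in untreated cells (0.630 to 0.635), and contacts at 1 to 2 Mb were 0.685 times. The corresponding TPA ratios were 0.703 and 0.773. On this scale the treatments differed at 5 to 10 Mb: the ATRA ratio was 0.951 (0.946 to 0.957) and the TPA ratio 1.19 (1.18 to 1.20). Beyond 50 Mb the ratios were 0.979 in ATRA and 1.08 in TPA. The decay of contacts with distance was shallower between 1 and 10 Mb, with a median slope over 23 chromosomes of -1.18 in untreated cells (quartiles -1.23 and -1.15), -1.003 in ATRA (-1.04 and -0.97) and -0.94 in TPA (-1.01 and -0.91). Between 10 and 100 Mb, over 20 chromosomes, the slopes were -0.66, -0.65 and -0.68, and their differences were smaller than the range between chromosomes.

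**Figure D1:**
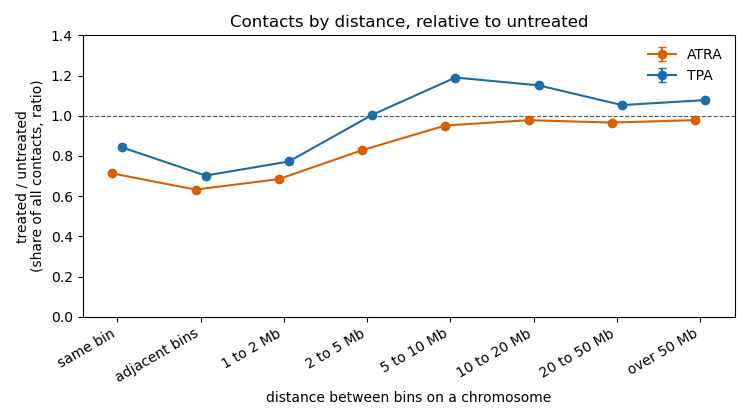
The vertical axis is the share of all contacts of a treated matrix at a given distance divided by the same share in the untreated matrix, and the horizontal axis is the distance between bins; points are 1 matrix each and the bars, mostly hidden by the points, are 95% counting intervals. Adjacent bins give 0.633 in ATRA and 0.703 in TPA, while the TPA ratio reaches 1.19 at 5 to 10 Mb.

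The division of chromosomes into an active (A) and an inactive (B) compartment was largely retained, with more change in TPA than in ATRA. Compartment scores are the leading eigenvector of each chromosome's contact pattern, in SD of the chromosome. A is the side in contact with gene-rich chromosome 19 in the summed matrix, so the side was not set in each matrix separately. Across 5630 bins, which are not independent replicates, scores correlated with those of untreated cells at r = 0.902 in ATRA and r = 0.786 in TPA. Matrices made by assigning each contact to a condition at random gave correlations of 0.947 to 0.955 for ATRA and 0.954 to 0.956 for TPA. Bins in A made up 46.0% of bins in untreated cells, 43.7% in ATRA and 42.3% in TPA. Counting as a switch a move from beyond 0.5 SD on one side to beyond 0.5 SD on the other, 27 bins went from A to B and 7 from B to A in ATRA. In TPA, 129 bins went from A to B and 60 from B to A. The random assignments gave at most 5 switches in either comparison.

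Chromosomes 14 and 21 were set apart because their leading eigenvector differed between matrices. On chromosome 14 the TPA scores correlated with the untreated scores at r = -0.65 and gave 48 A to B and 40 B to A switches, and on chromosome 21 the ATRA correlation was 0.464. Without them, a choice made after the data were seen, 24 bins went from A to B and 4 from B to A in ATRA, and 78 and 18 did so in TPA, among 5384 bins. The correlations were then 0.908 in ATRA and 0.834 in TPA. Chromosome 9 was kept although its TPA correlation, 0.664, was below that of chromosome 21 in TPA, 0.717. Chromosomes 3 (0.729) and 5 (0.749) were also kept, and chromosome 3 gave 18 A to B switches in TPA. In the summed matrix, scores of chromosomes 3 and 5 followed contact with chromosome 19 only weakly, at correlations of 0.261 and 0.228. Switches on these chromosomes may therefore be less certain. Without correction for bin coverage, over all chromosomes, the excess of A to B switches turned around in ATRA (53 A to B and 61 B to A) and was smaller in proportion in TPA (258 and 215).

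Outside these chromosomes, the bins with the largest falls in ATRA lay at 114.0 to 114.5 Mb of chromosome 9 (score 1.00 in untreated, -0.84 in ATRA), 95.5 to 96.0 Mb of chromosome 2 (0.57 to -1.08), 226.5 to 227.0 Mb of chromosome 1 (0.89 to -0.74), 42.5 to 43.0 Mb of chromosome X (0.87 to -0.69) and 45.5 to 46.0 Mb of chromosome 7 (0.64 to -0.89). All 4 rises in ATRA were at 92.5 to 93.0 Mb of chromosome 12 (-0.70 to 0.96), 101.0 to 101.5 Mb of chromosome 1 (-0.57 to 0.80), 75.0 to 75.5 Mb of chromosome 9 (-0.56 to 0.57) and 143.0 to 143.5 Mb of chromosome 6 (-0.51 to 0.55). By the eigenvector of contacts between chromosomes, the falls in this order scored 0.05, 0.58, -0.15, 0.67 and -0.25 in untreated cells. In ATRA they scored -0.18, -0.77, -0.50, -0.63 and -0.68. By that measure the rises went from -0.66 to 0.26, -0.47 to 0.02, -0.53 to -0.11 and -0.60 to 0.13. The largest falls in TPA lay at 77.5 to 78.0 Mb of chromosome 4 (1.52 to -0.86), 134.5 to 135.0 Mb of chromosome 3 (0.80 to -1.57), 89.0 to 89.5 Mb of chromosome 9 (0.82 to -1.52), 21 to 21.5 Mb of chromosome 8 (1.13 to -1.19) and 87.0 to 87.5 Mb of chromosome 9 (0.86 to -1.36). The largest rises in TPA lay at 2.5 to 3.0 Mb of chromosome 9 (-0.51 to 1.26), 92.5 to 93.0 Mb of chromosome 12 (-0.70 to 1.02), 7.0 to 7.5 Mb of chromosome X (-0.73 to 0.96), 22 to 22.5 Mb of chromosome 9 (-0.74 to 0.89) and 98.0 to 98.5 Mb of chromosome 3 (-0.54 to 1.06). By contacts between chromosomes, the falls in TPA scored 0.67, -0.24, -0.33, 0.30 and -0.36 in untreated cells, in this order. In TPA they scored -0.26, -1.05, -0.86, -0.64 and -0.78. The rises went from -0.35 to 0.12, -0.66 to 0.22, -0.65 to -0.63, -0.45 to 0.24 and -0.17 to -0.004. By that measure, in both treatments, not all falls began in A and not all rises ended there.

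With all chromosomes included, the naming rule gave mostly bins of chromosomes 14 and 21. In ATRA the falls on chromosome 21 were at 9.5 to 10.0 Mb (1.86 to -0.77), 11 to 11.5 Mb (1.65 to -0.94) and 15.0 to 15.5 Mb (0.65 to -1.12), and the rises were at 34 to 34.5 Mb (-0.51 to 1.59), 36.0 to 36.5 Mb (-0.56 to 1.28) and 37.0 to 37.5 Mb (-0.85 to 0.66). In TPA all 5 falls and all 5 rises were on chromosome 14. The falls started at 49, 60, 82.5, 85 and 88 Mb, and the rises covered 73.5 to 76.0 Mb, where the largest change was from -1.82 to 2.27. By the eigenvector of contacts between chromosomes, all these bins of chromosomes 14 and 21 kept their side. On chromosome 14 the rises scored 0.85 to 1.35 in untreated cells and 1.31 to 2.34 in TPA. The falls scored -0.98 to -0.43 in untreated cells and -0.83 to -0.43 in TPA. These bins are therefore not read as moves between compartments.

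**Figure D2:**
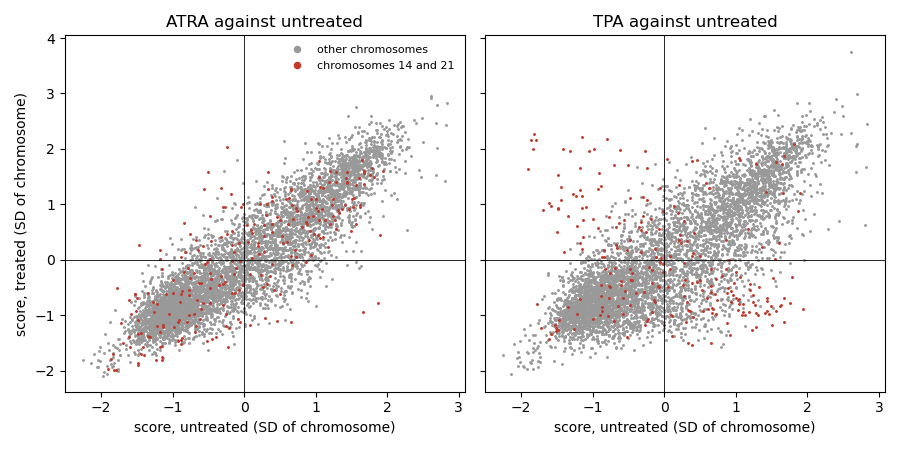
Each point is a 500 kb bin, with its compartment score in untreated cells on the horizontal axis and in ATRA (left) or TPA (right) on the vertical axis, both in SD of the chromosome; red points are bins of chromosomes 14 and 21. Most points follow the diagonal, while in the TPA panel the bins of chromosome 14, with a correlation of -0.65, run against it and those of chromosome 21, with 0.717, do not.

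Adjacent bins switched together at 12 places in TPA and 1 place in ATRA outside chromosomes 14 and 21. The segment at 95.5 to 96.5 Mb of chromosome 2 went from A to B in both, with a mean score of 0.54 in untreated cells, -0.80 in ATRA and -1.14 in TPA. This segment borders a run of low coverage at 92.5 to 95.5 Mb that holds the largest gap of the chromosome, so its scores may be less certain. On chromosome 5 the 3 bins from 173.5 to 175.0 Mb went from 0.93 to -0.80 in TPA, with 0.17 in ATRA. The segment at 89.0 to 90.0 Mb of chromosome 9 went from 0.80 to -1.40 in TPA and measured 0.81 in ATRA. Chromosome 3 held 4 such segments in TPA, starting at 43.5, 53.5, 55.5 and 123.5 Mb. The 1 segment that went from B to A lay at 57.0 to 58.0 Mb of chromosome 16, from -0.69 to 0.53.

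ATRA and TPA scores resembled each other about as closely as ATRA resembled untreated. Without chromosomes 14 and 21, they correlated at r = 0.897, with 14 bins in A in ATRA and in B in TPA, and 7 the other way. Of the 24 and 78 A to B bins, 18 were shared, among them bins at 123.5 and 134.5 Mb of chromosome 3, 16.0 Mb of chromosome 17 and 112.0 Mb of chromosome 13. Independent lists drawn from all 5384 bins would share 0.348 bins. Both lists can only hold bins in A in the same untreated matrix, so this expectation is too low. The random assignments, which use the same untreated matrix for both, gave at most 1. With the untreated contacts split at random and 1 part used for each treatment, 6 bins were shared in either arrangement. Part of the overlap may therefore come from the shared untreated matrix. The split also lowered the untreated depth for each treatment, which may reduce the overlap by itself. Sharing and depth cannot be told apart here. Changes in score correlated at 0.628 between the treatments, against 0.492 under random assignment, and their covariance was 0.155 against 0.042. With the untreated contacts split, the correlation was 0.414 and the covariance 0.113, with the same limit of depth.

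Contacts between A bins and between B bins exceeded contacts between A and B bins by a factor (saddle strength) of 3.01 in untreated cells, 2.96 in ATRA and 2.68 in TPA. The TPA ratio to untreated was 0.892 with a counting SD of 0.0078. The ATRA ratio was 0.983 with a counting SD of 0.0084, and it moved above 1, to 1.02, when eigenvectors were computed per arm or when every matrix was ordered by the scores of the summed matrix, so no direction is given for ATRA.

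Contacts among the small, gene-rich chromosomes 17, 19, 20 and 22 were weaker in both treated matrices. The pair of chromosomes 19 and 22 had the highest ratio of observed to expected contacts in untreated cells, 2.02, and measured 1.43 in ATRA and 1.48 in TPA. Their contacts numbered 9168, 4756 and 6693. The log2 change of the ratio was -0.50 in ATRA (-0.55 to -0.45) and -0.44 in TPA (-0.49 to -0.40), the largest fall of any pair in each. With the expectation from chromosome lengths it was -0.97 in ATRA and -0.49 in TPA. Chromosomes 17 and 19 changed by -0.36 in ATRA and -0.36 in TPA, and chromosomes 19 and 20 by -0.33 and -0.30. Next came chromosomes 16 and 19 (-0.23) and 17 and 22 (-0.19) in ATRA, and 17 and 22 (-0.29) and 17 and 20 (-0.23) in TPA. All 6 pairs among chromosomes 17, 19, 20 and 22 had lower values in each treated matrix, with a median log2 change of -0.26 in ATRA and -0.30 in TPA.

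Relative to coverage, the pairs that rose most joined chromosomes 19 or 22 with chromosomes 4, 6, 7, 13 or X. The expectation is fitted to the coverage of each chromosome, so falls with some partners raise the values of others, and the size of these rises depends partly on those falls. In number, contacts of chromosomes 4 and 19 went from 14607 in untreated cells to 14842 in ATRA and 17828 in TPA, those of 13 and 22 from 6618 to 6735 and 8268, and those of 7 and 19 from 12847 to 12529 and 14560. Not all pairs with larger chromosomes rose, and chromosomes 1 and 19 changed by -0.04 in ATRA and -0.08 in TPA. In ATRA the largest rises joined chromosome 19 with chromosomes 13 (0.21), 6 (0.20), X (0.20), 4 (0.18) and 7 (0.17). In TPA they joined chromosomes 13 and 22 (0.27, 0.22 to 0.31), 4 and 19 (0.20), 4 and 22 (0.19), 19 and X (0.19) and 13 and 19 (0.18). Over all pairs of chromosomes the log2 ratios were compressed, with a slope on the untreated values of 0.715 in ATRA and 0.766 in TPA. The other pairs with the highest ratios in untreated cells were 20 and 22 (1.77), 3 and 14 (1.71), 17 and 22 (1.66) and 17 and 19 (1.65). Chromosomes 3 and 14 measured 1.55 in ATRA and 1.70 in TPA.

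**Figure D3:**
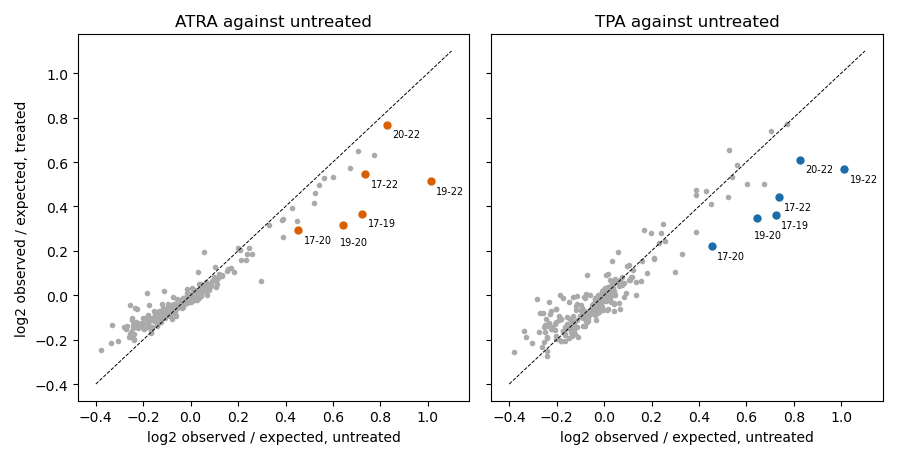
Each point is a pair of chromosomes, with the log2 ratio of observed to expected contacts in untreated cells on the horizontal axis and in ATRA (left) or TPA (right) on the vertical axis; the dashed line marks equal values and coloured points are the 6 pairs among chromosomes 17, 19, 20 and 22. The coloured points lie below the line in both panels, with chromosomes 19 and 22 at 1.01 in untreated cells, 0.51 in ATRA and 0.57 in TPA.

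Coverage of bins moved with compartment and chromosome. The median bin of chromosome 19 had a log2 coverage ratio to untreated of -0.43 in ATRA (quartiles -0.56 and -0.23) and -0.16 in TPA (-0.22 and -0.08). Chromosomes 22 and 17 followed, at -0.27 and -0.21 in ATRA and -0.13 and -0.12 in TPA. With contacts between chromosomes alone, the chromosome 19 ratio was -0.32 in ATRA and -0.01 in TPA. Outside chromosomes 14 and 21, bins beyond 0.5 SD in the summed matrix numbered 1813 in A and 2309 in B. Their median log2 ratio was -0.13 in A and 0.07 in B in ATRA, and -0.08 and 0.06 in TPA. With contacts between chromosomes alone, it was -0.12 and 0.07 in ATRA, and less in TPA, -0.04 and 0.02.

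The larger joined segments stood out in all 3 matrices. Segments of different chromosomes in contact at 10 or more times the level that coverage predicts formed 144 clusters, of which 37 held at least 5 bin pairs and 72 a single pair. Clusters were called on the 3 matrices summed, and the smaller ones rest on few contacts, down to 1 in a matrix. The 37 larger ones held at least 30 contacts and 8.91 times the expected number in each matrix. The cluster with the most contacts, 4104, linked 116.5 to 121.0 Mb of chromosome 6 with 126.0 to 131.0 Mb of chromosome 8, at 14.5 times expected in untreated cells, 10.3 in ATRA and 14.6 in TPA. The next linked 1.0 to 10.0 Mb of chromosome 1 with 182.0 to 197.5 Mb of chromosome 3 (21.9, 15.3 and 18.1 times). Chromosome 5 at 148.5 to 160.5 Mb met chromosome 16 at 77.5 to 86.5 Mb (19.8, 12.4 and 19.6 times). Chromosome 4 at 183.5 to 191.0 Mb met chromosome 18 at 40.5 to 49.5 Mb (29.4, 20.8 and 28.5 times). Chromosome 16 at 23 to 31.5 Mb met chromosome 21 at 30.5 to 35.0 Mb (30.3, 20.2 and 23.6 times). Chromosome 7 at 131.0 to 136.0 Mb met chromosome 16 at 77.5 to 85.5 Mb (17.6, 13.97 and 18.0 times). Chromosome 14 took part in 3 of the 10 clusters with the most contacts. It met chromosome 3 at 189.0 to 197.0 Mb (21.1, 15.2 and 17.6 times), chromosome 21 at 37.5 to 41.5 Mb (19.1, 11.3 and 13.8 times) and chromosome 9 at 107.0 to 112.5 Mb (26.5, 20.2 and 25.0 times). The remaining cluster linked 8.0 to 15.0 Mb of chromosome 16 with 25.5 to 30.0 Mb of chromosome 17 (16.3, 13.3 and 14.8 times). Among clusters of at least 5 pairs, chromosome 16 had the most partners, 5, namely chromosomes 1, 5, 7, 17 and 21. The rule does not separate joined chromosomes from reads placed on the wrong chromosome, which was not tested. Any of these clusters, and so any of these partners, may therefore not be a join.

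**Figure D4:**
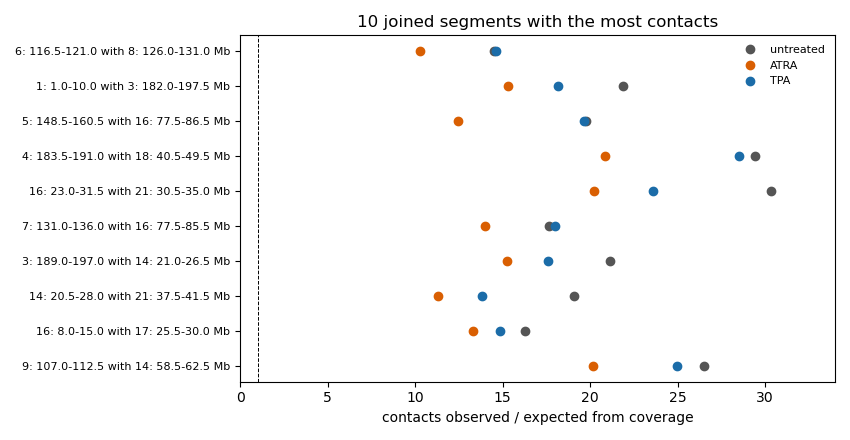
The horizontal axis is the ratio of observed contacts to those expected from coverage and each line is 1 of the 10 clusters with the most contacts; points are the 3 matrices and the dashed line marks 1. Every point lies far to the right of the line, between 10.3 and 30.3, and ATRA is the lowest of the 3 in each cluster.

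A segment of the long arm of chromosome 8, the arm that holds MYC, had high coverage at a similar level in every condition. MYC encodes a growth-promoting transcription factor and is amplified in HL60. The run at 126.0 to 127.5 Mb lay at 10.8 times the median bin in untreated cells, 10.5 in ATRA and 10.96 in TPA. Further high bins started at 128.0, 128.5, 130.0 and 130.5 Mb, with up to 15.7, 16.2 and 15.2 times the median at 130.0 Mb. Between them, bins starting at 127.5 and 129.5 Mb lay at 0.966 and 0.956 in untreated cells. Low coverage in all 3 matrices, under 0.4 times the median over at least 3 bins, was found in 45 runs, of which 23 held the largest gap of their chromosome or the start of an acrocentric one. The longest covered 39.0 to 68.0 Mb of chromosome 9, 121.5 to 142.5 Mb of chromosome 1 and 35.0 to 46.5 Mb of chromosome 16, together with the starts of chromosomes 13, 14, 15, 21 and 22 up to 19, 20, 22.5, 9.5 and 17 Mb. The longest elsewhere was at 88.0 to 94.5 Mb of chromosome X, whose median bin lay at 0.442 times that of the genome, and this run lay at 0.451 times the chromosome's own median in untreated cells.

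**Figure D5:**
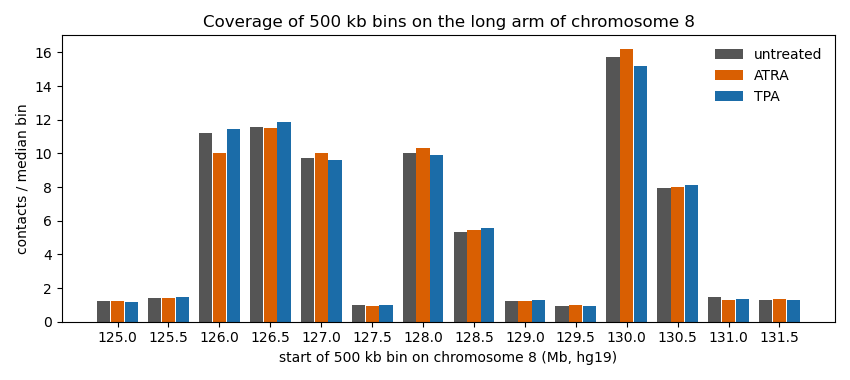
Bars give the contacts of each 500 kb bin divided by the median bin of the same matrix, for bins along the long arm of chromosome 8 on hg19; colours are the 3 matrices. The bars rise to 15.7, 16.2 and 15.2 at 130.0 Mb and stay near 1 between the high bins.

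Few single bin pairs met the rule for a difference between treated and untreated cells. Recovery by this rule was not tested for changes below 3-fold, so smaller differences may have been missed. Among pairs with at least 50 contacts, a pair had to change at least 2-fold (log2 of 1) and by more than 5 counting SEs. In ATRA 2 of 9905 pairs within chromosomes and 0 of 409 between chromosomes met this rule. The contact of 125.0 to 125.5 with 126.0 to 126.5 Mb on chromosome 10 was higher in ATRA (141 contacts against 90, log2 ratio to distance expectation 1.39, 1.01 to 1.77), with 93 contacts in TPA. The contact of 138.0 to 138.5 with 139.0 to 139.5 Mb on chromosome 9 was lower (41 against 161, -1.26, -1.76 to -0.77), with 98 in TPA. With an expectation from balanced contacts, chosen after the data were seen, 7 pairs within chromosomes met the rule in ATRA and 0 in TPA. In TPA 2 of 11573 pairs within chromosomes were higher, and 0 met the rule after thinning to equal total contacts, which left contacts within chromosomes unequal. They were 147.5 to 148.0 with 149.0 to 149.5 Mb of chromosome 7 (51 against 13, 2.25, 1.39 to 3.11) and 78.5 to 79.0 with 79.5 to 80.0 Mb of chromosome 16 (120 against 83, 1.06, 0.66 to 1.47). One of 474 pairs between chromosomes was lower in TPA, 28.0 to 28.5 Mb of chromosome 16 with 33.5 to 34 Mb of chromosome 21 (36 against 100, -1.54, -2.08 to -0.99), and it had 47 contacts in ATRA. Between ATRA and TPA, 0 of 8765 pairs within chromosomes met the rule. Pairs within chromosomes beyond 3 counting SEs made up 1.87% in ATRA and 2.13% in TPA, against 0.222% and 0.225% under random assignment. Of pairs between chromosomes, 28 of 409 (6.85%) in ATRA and 8 of 474 (1.69%) in TPA were beyond 3 SEs, against 0 under random assignment, and the median log2 ratio was -0.36 in ATRA and -0.13 in TPA. A bin pair held 0.52 to 0.57 contacts on average, so pairs between chromosomes with at least 50 are a set with unusually many contacts. Their medians do not describe contacts between chromosomes in general.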

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

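In this part, the tests of bin coverage and of the change of A to B bins between chromosomes were set before their results were seen; the tests of random ligation, of neighbouring fragments, of counting noise, of the eigenvectors of chromosomes 14 and 21 and of the share of A to B switches between chromosomes were chosen after. Counting noise was first read as open in ATRA from all switches, where random assignment gave 0.118 times as many against a limit of 0.1, and is now read on the excess of A to B. The share of A to B switches between chromosomes was first read with bins as units, then with chromosomes, with the same outcome. The random ligation, counting noise and eigenvector tests were also split by treatment after pooled values had been seen. Random ligation as the cause of the weaker contacts among gene-rich chromosomes was first read as excluded; once split and held to its counting interval and to balanced bins as well, it became open in ATRA. The fit for contacts under 2 Mb was changed from least squares to the smallest largest departure, with the same outcome. In all, 7 versions of the analysis were run in full; chromosome arms were redefined after the first, and the rule that marks a reversed result was corrected before the fourth, which marked 4 values as reversed, 2 of them for the balance of switches, a result added then.

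Contacts of mitochondrial with nuclear DNA, which lie outside the chromosomes compared in the report, were more frequent in the treated matrices than in the untreated one, for every 1000000 contacts at 836.9 in ATRA (818.7 to 855.3) and 639.9 in TPA (624.6 to 655.4) against 339.7 in untreated cells (328.7 to 350.9).

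Both treated matrices held fewer contacts under 2 Mb. Random ligation as the only source would make treated contacts a scaled copy of the untreated ones plus a background set by coverage; the best such fit left a distance class off by 11.8% in ATRA (11.5 to 12.0) and 16.5% in TPA (16.3 to 16.6), beyond the limit of 10%. Loss of neighbouring fragments in filtering would end beyond adjacent bins, yet contacts at 1 to 2 Mb relative to untreated were still 0.720 times those at 5 to 10 Mb in ATRA, and lower in TPA. A partial contribution of random ligation may remain, also to the lower share of contacts within chromosomes, for which it was not tested, since the mitochondrial contacts above rose in both. A treatment effect cannot be told apart from a library effect, because each condition has its own libraries and no replicate matrix.

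Contacts among chromosomes 17, 19, 20 and 22 were weaker in both treated matrices. Bias from GC content or HindIII sites that acts on each bin separately would vanish once every bin is balanced. The smaller of the 2 median log2 changes was still -0.26. Balancing cannot remove a bias that depends on both bins of a pair together, so such a bias stays open. Random ligation as the only change would shrink the excess of joined segments and of these pairs by the same factor. In TPA the factors were 0.882 and 0.517, a difference of 0.365 (0.331 to 0.395), which argues against it as the only change. The factor of joined segments may also hold changes with distance like those within chromosomes. At 5 to 10 Mb, contacts within chromosomes were 1.19 times untreated in TPA and 0.951 times in ATRA. A partial contribution of random ligation therefore stays open in TPA. In ATRA the factors were 0.699 and 0.582, a difference of 0.118 (0.0927 to 0.141), or 0.0984 with every bin balanced, so random ligation stays open there. Library effects also stay open in TPA, and no biological explanation was tested.

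Switches from A to B outnumbered those from B to A in both treated matrices. Counting noise is argued against, since 5 random assignments gave an excess of at most 1 bin in ATRA and 1 in TPA, against 20 (8.57 to 31.4 if bins are independent) and 69 (42.1 to 95.9) observed. Unstable eigenvectors on chromosomes 14 and 21 are not the whole cause, since without them A to B switches were 6 times as many as B to A switches in ATRA and 4.33 times in TPA, and the best-matching of the first 3 eigenvectors left the counts there unchanged at 24 and 4, and 78 and 18 (over all chromosomes 49 and 39, and 93 and 30). With the eigenvector of contacts between chromosomes, the A to B bins changed relative to all A bins by a median of -0.589 SD in ATRA (-0.805 to -0.462). In TPA the median was -0.774 (-0.883 to -0.696). By that eigenvector, however, A to B was only 54.2% of switches in TPA, or 56.5% without chromosomes 14 and 21. Without them, A to B was more frequent on 5 chromosomes and less on 4. In TPA an excess limited to contacts within chromosomes therefore cannot be told apart. In ATRA A to B was 83.3% of 12 switches (6 and 0 chromosomes, 54.1 to 100% if chromosomes are independent), which is weak evidence against such a limited excess. The excess may still depend on the correction for coverage, since with unbalanced contacts A to B minus B to A switches were -0.142% of bins in ATRA and 0.764% in TPA, against 0.355% and 1.23%; at a threshold of 1 SD they were -0.231% in TPA, carried by chromosomes 14 and 21, without which 1 bin went from A to B and 0 from B to A.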

How the results depend on the processing

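Alternatives on the best-matching eigenvector, on leaving out chromosomes 14 and 21, on their combination with a threshold of 1 SD, on scores of the summed matrix, on balancing every bin and on a balanced distance expectation were chosen after seeing the data. Over 34 results and 153 alternative values, 4 reversed, 71 stayed within counting error (for counts, within 1.5 times) and 78 moved; except where stated, the cause was not tested. No paired analysis was possible because the untreated and TPA libraries numbered 1 and 2 are merged in 1 matrix each. For the same reason the replicate block and leaving out each replicate were not run, and the gene lists were not run because no gene was placed in a bin. With 0.52 to 0.57 contacts per bin pair, depth limits single pairs more than sums.

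Without contacts inside a bin, the cis share differed by -6.18 points in ATRA and -1.90 in TPA. With balanced contacts, the share under 2 Mb differed by -6.67 points in ATRA and -8.34 in TPA, the 1 to 10 Mb slope by 0.16 in ATRA and the 10 to 100 Mb slope by -0.03 in TPA (-0.0282); leaving out bins of low coverage gave -0.0259 for the latter.

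Score correlations with untreated in ATRA were 0.854 in 1 Mb bins, 0.799 with raw contacts, 0.919 with contacts between chromosomes, 0.896 per arm, 0.869 with the best-matching eigenvector and 0.908 without chromosomes 14 and 21. In TPA they were 0.554 with raw contacts and 0.872 with contacts between chromosomes. Saddle strength over untreated in ATRA was 0.950 in 1 Mb bins, 0.812 with raw contacts, 0.949 with contacts between chromosomes, 1.02 per arm (1.024) and 1.02 by summed scores (1.017); the last 2 reversed the direction. In TPA it was 0.791, 0.680, 0.972, 0.942 and 0.916, below 1 in each.

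A to B switches in ATRA took 1.38% of bins at 1 Mb, 0.941% with raw contacts, 0.178% with contacts between chromosomes, 6.79% at a threshold of 0 SD, 0 at 1 SD and 0.870% with the best-matching eigenvector. B to A switches in ATRA took 0.884%, 1.08%, 0.0355%, 4.48%, 0 and 0.693% in the same order, and 0.0743% without chromosomes 14 and 21. In TPA, A to B switches took 4.58% with raw contacts, 0.231% with contacts between chromosomes, 10.4% at 0 SD, 0.0888% at 1 SD and 1.45% without chromosomes 14 and 21. B to A switches took 3.82%, 0.195%, 6.68%, 0.320% and 0.334%, and 0.533% with the best-matching eigenvector. The difference of A to B minus B to A reversed in ATRA with raw contacts (-0.142 points) and in TPA at 1 SD (-0.231). The latter comes from chromosomes 14 and 21, without which A to B switches at 1 SD took 0.0186% of bins in TPA and B to A switches 0, a difference of 0.0186 points, with 0 of either in ATRA. It was 0.142 points in ATRA and 0.0355 in TPA with contacts between chromosomes, 2.31 and 3.73 at 0 SD, and 0 in ATRA at 1 SD.

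Splitting the untreated contacts gave a correlation of 0.357 and a covariance of 0.113 for the shared change, and leaving out chromosomes 14 and 21 a correlation of 0.628 (0.414 with the split as well). The slope of chromosome pair contacts on untreated in ATRA and TPA was 0.705 and 0.751 without joined segments, 0.847 and 0.917 with chromosome lengths, and 0.726 and 0.738 with every bin balanced. Chromosomes 19 and 22 changed by -0.97 in ATRA with chromosome lengths. From contacts between chromosomes alone, chromosome 19 coverage was -0.32 in ATRA and -0.01 in TPA (-0.0080), and the chromosome 8 segment stood at 11.7 in untreated cells, 11.04 in ATRA and 11.8 in TPA. At 20 times expected there were 48 joined clusters. Pairs past the rule within chromosomes became 7 in ATRA and 0 in TPA with a balanced expectation. In TPA they became 1 at 100 contacts and 0 after thinning to equal total contacts.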

Other observations

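The test of a deleted segment below was set before its result was seen, and the regions in this part were chosen after their values were seen.

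As ratios to untreated, short-range contacts fell by similar amounts in both compartments, while contacts over 10 Mb differed between them. With A and B as beyond 0.5 SD in the summed matrix, outside chromosomes 14 and 21, bins of A (1813) had a median log2 ratio to untreated for contacts under 2 Mb of -0.60 in ATRA and -0.48 in TPA, and bins of B (2305) had -0.62 and -0.43. For contacts over 10 Mb, bins of A had -0.15 in ATRA and -0.01 in TPA, and bins of B had 0.06 and 0.24. The quartiles in TPA over 10 Mb were -0.13 and 0.12 in A, and 0.12 and 0.35 in B. Coverage by all contacts also moved, by a median of -0.13 in A and 0.07 in B in ATRA, and -0.08 and 0.06 in TPA. The difference over 10 Mb may therefore not be particular to long-range contacts, most of all in ATRA. Relative to coverage, the short-range loss may differ between the compartments.

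Chromosome 16 at 28.0 Mb and chromosome 21 at 33.5 Mb, the strongest bin pair of their joined segments at 107 times expected over 183 contacts, held 100 contacts in untreated cells, 47 in ATRA and 36 in TPA. The whole cluster changed less, from 781 contacts in untreated cells to 506 in ATRA and 622 in TPA.

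A segment of chromosome X at 145.0 to 149.0 Mb had almost no contacts in any matrix, at 0.0300 times the median bin in untreated cells, 0.0305 in ATRA and 0.0330 in TPA. A deletion in the line may be a hypothesis, in which case the bins on either side would touch more often than their distance predicts. They did so at 2.17 times expected over 351 contacts, below the 3 times set for a deletion and above the 1.5 times set against one. By the same measure 18 runs that hold the largest gap of their chromosome had a median of 1.15 and a range of 0.507 to 3.18, with 3 above the segment (chromosomes 7, 1 and 11) and 15 below it. By this measure a deletion and a segment that reads cannot cover were not told apart. Whether reads can be placed in this segment was not examined. Unlike the 18 runs, it does not hold the largest gap of its chromosome.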
